A study of Mus musculus with 38 samples.

How the data were processed

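RNA was measured in microdissections of the anterodorsal bed nucleus of the stria terminalis (adBNST) of wild-type mice of both sexes. The 38 libraries were placed in 4 groups from their titles and sex and treatment labels. There were 10 libraries of control females, 9 of stressed females, 10 of control males and 9 of stressed males. Per the labels' protocols, total RNA was extracted with a micro-scale column kit, mRNA was enriched by its poly-A tail and stranded libraries were made. The same protocols describe chronic variable mild stress over 6 weeks with randomised stressors.

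The deposited table held raw counts of reads per gene symbol, 1 column per library, with no scaling applied, as judged from whole numbers whose totals differed between libraries. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mm10 genome build, without versions. The annotation, the strand setting of the counting and any filter are not given in the sources used here. Genes that overlap on opposite strands or that share sequence with near-identical copies, such as ribosomal protein genes with their pseudogenes, are therefore less certain than others. Every column of the table was matched to a library by name, and 0 columns of other samples were left over. The table had 25230 genes, of which 3439 had no count in any library. The symbols of 24930 genes, 16194 of them among those tested, were matched to RefSeq's annotation of GRCm38.p6, the assembly that mm10 names, for coordinates. Transcript lengths, and the share of each gene's 50-base words that also occur in other genes, came from GENCODE M21 transcripts and covered 16036 tested genes.

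Total counts ranged from 9.1 to 84.8 M per library, with a median of 27.35 M. A single count was worth 0.012 CPM in the deepest library and 0.11 CPM in the shallowest. The 45S ribosomal RNA precursor Rn45s took 0.121% to 4.81% of the counts. Levels are given as CPM, computed here from the deposited counts on the effective library sizes. The closest libraries of each group differed by far more than counting noise, with a chi-square per gene of 8.19, 13.7, 19.8 and 10.4, so no library was treated as a copy of another.

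Before the data were examined, the tests, alternatives, gene lists and the rule for naming genes were written down. Genes were tested with edgeR's quasi-likelihood test on the counts, after filterByExpr by group and TMM normalisation, with a mean for each of the 4 groups and shared dispersion, which is the model of sex, condition and their interaction that the series describes. The filter left 16309 genes and removed 8921. The biological coefficient of variation was 0.266. Contrasts were stress in females, stress in males, the difference of these effects (males minus females, the interaction), stress averaged over the sexes, and male minus female in controls and in stressed mice. P-values were adjusted by Benjamini-Hochberg over the genes tested in each contrast, and a gene passed at an adjusted p under 0.05. Fold changes are log2 values with their standard errors.

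The naming rule took the 10 genes with the smallest p in each direction among those that passed, leaving out sex-linked genes listed beforehand, or 3 where fewer than 3 passed. It added up to 4 passing members of each gene list, or 2 members of a list called without a passing member, and a panel of 17 genes reported whatever the result. A further panel gene and a list member chosen by this rule are not reported here, for a reason unrelated to their values, and some other list members are left out for length. Unnamed gene models were passed over. Where a gene falls outside this rule, the text says so.

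There were 39 gene lists, 23 of processes and 16 of cell types or neighbouring regions. They are named in the figure of list medians or in the report, and the KCNQ list also holds HCN and T-type calcium channels. A list of mitochondrially encoded genes had 0 members in the table, and the blood list had 1 tested member, so neither entered the set test. Lists were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, with camera's estimated correlation, and with fry. Adjustment was over lists within a contrast. Counts of members that passed are given over all genes and adjusted over the list alone. The score of a list in a library is the mean over its members of log2 CPM (prior count 2) centred on all libraries. Scores were compared between groups with two-sided permutation tests, exact where a group had 9 libraries and with 100000 resamples for 10 against 10, adjusted over 38 lists. Exact tests with libraries exchanged only within each number set used the mean of the differences in the sets, weighted by their sizes. All score tests were chosen after seeing the data.

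Alternatives planned beforehand were DESeq2's size factors, no low-count filter, DESeq2, limma voom with quality weights, the replicate number as a block, a 2-level term for replicate numbers up to 5 against 6 and above, surrogate variables from sva (5 were estimated), 4 marker scores as covariates, only the compared groups, a threshold of 0.10, and leaving out each library. Settings added after seeing the data left out 5 libraries that stood apart on the first principal component or male stressed library 5, or used the libraries of either number range alone. In all, 53 refits of the gene test were made beside the planned design, 9 of them planned, 6 added and 38 leaving out a library.

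Other splits of the libraries into groups of the same sizes were fitted 100 times per comparison, the real split included. After the results were seen, 100 splits that exchanged libraries only within each number set were added. Principal components used the 1000 most variable genes. The procedure was tested on simulated counts for the 16309 genes with 200 genes changed by known folds. With 50 genes at each fold, edgeR recovered 48% of 1.5-fold and 80% of 2-fold changes for stress in females, 38% and 76% for stress in males, and 22% and 56% for the interaction. It recovered 64% and 86% for the average, 44% and 76% for male minus female in controls and 52% and 78% in stressed mice. Whether real data give these shares was not tested. Of simulated calls between the sexes in controls and stressed mice, 1.71% and 5.74% were false for edgeR. DESeq2 gave 10.5% and 12.3% and limma 6.72% and 6.4%.

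Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.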

Results

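Gene expression was measured in the anterodorsal bed nucleus of the stria terminalis (adBNST), a small forebrain nucleus that takes part in anxiety and in the control of the stress axis. Tissue came from wild-type male and female mice that were either left undisturbed or exposed for 6 weeks to randomised mild stressors. Poly-A RNA from 38 microdissections gave 10 libraries of control females, 9 of stressed females, 10 of control males and 9 of stressed males. Total counts ran from 18.1 to 33.8 M in control females, 14.6 to 35.3 in stressed females, 9.1 to 84.8 in control males and 15.9 to 36.1 in stressed males. Of 25230 genes, 16309 were tested. The labels number the libraries but do not state that each came from a separate animal, so the p-values below measure the spread between libraries. Levels are CPM as mean ± SD with n = 10 for control and n = 9 for stressed groups, and changes are log2 values ± SE.

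Sex-linked transcripts matched the sex labels of every library. Xist, the RNA that coats the inactive X, ran from 305.9 to 2156 CPM in females and reached at most 0.927 CPM in males. Ddx3y, an RNA helicase of the Y chromosome, ran from 39.6 to 139.8 CPM in males and had at most 1 count in a female library. The Y-linked demethylases Kdm5d and Uty had 0 counts in all female libraries and ran from 13.97 to 68.7 and from 9.05 to 35.8 CPM in males.

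The third principal component (10.7% of the variance, 13.6% on the second) separated the sexes (females up to 1.2, males from 4.7). On the first (32.5%) 5 libraries stood apart, female control 1 and 6, male control 3 and female stressed 1 and 2. They held more of the myelin transcript Mbp (9034 to 13349 CPM against 1830 to 6429 in the other 33), of the astrocyte filament Gfap (121 to 458 against 47.7 to 116.9) and of Npy (98.6 to 218 against 39.2 to 73.1). Male stressed library 5 held transcripts of choroid plexus, the epithelium that makes cerebrospinal fluid, with Ttr at 2878 CPM against at most 41.1 elsewhere, Kl at 139 against 14.98 and F5 at 51.8 against 2.81. Libraries numbered up to 5 also differed from those numbered 6 and above, for 7409 genes in a test within groups, 495 of them at least 2-fold. Sumo2 stood at 12.55 and 0.477 CPM in these sets, the ribosomal protein gene Rps29 at 266 and 44.8, Mbp at 5588 and 3136 and the ciliary factor Foxj1 at 18.1 and 39.1. Both sets held libraries of all 4 groups, 5 each up to 5, then 5 of each control and 4 of each stressed group, and values within each set are given below where they matter.

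**Figure D1:**
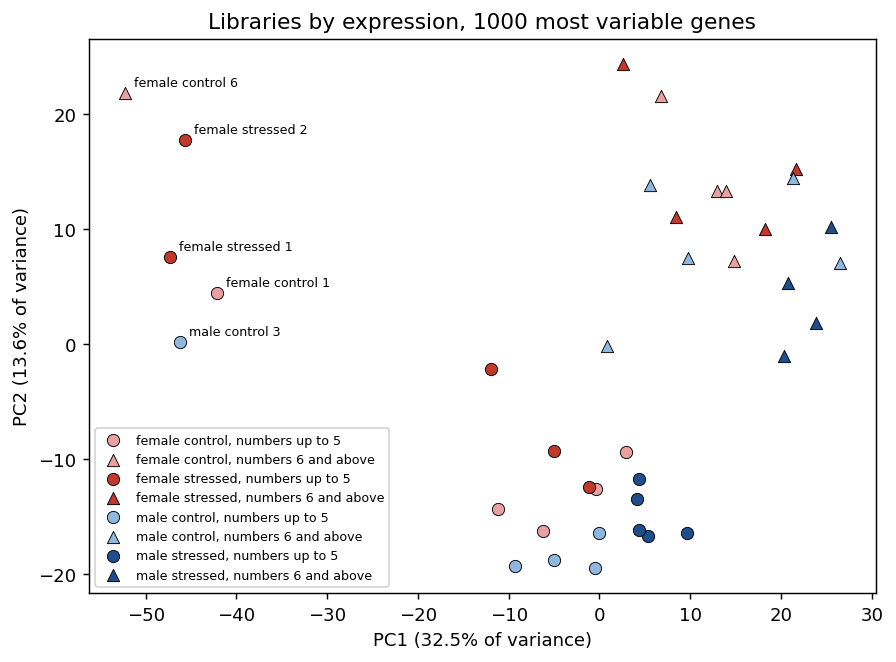
Libraries on the first 2 principal components of the 1000 most variable genes, by group and number set. The 5 labelled libraries stood apart on the first component.

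Genes of potassium channels and of NPY neurons, the subject of the series, were followed whatever their result. Stress gave -0.076 ± 0.19 for Kcnq3 and 0.053 ± 0.17 for Kcnq5 in females, and 0.046 ± 0.19 and 0.048 ± 0.17 in males. Npy, a peptide that dampens anxiety-like behaviour, stood at 77.7 ± 47.8 and 92.5 ± 69 CPM in control and stressed females and at 59.3 ± 17.7 and 48 ± 6.72 in males, a stress difference of 0.25 ± 0.28 and -0.30 ± 0.28 and an interaction of -0.55 ± 0.39. None of these passed edgeR's test (adjusted p = 1 in females, 0.864 in males and 0.846 for the interaction). The Npy value in females took opposite signs in the number sets, 0.61 ± 0.42 up to 5 and -0.41 ± 0.25 from 6, and was 0.058 ± 0.11 without the 5 libraries that stood apart. In males it was -0.19 ± 0.42 and -0.43 ± 0.25 in the number sets.

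Other panel genes also did not pass for stress in either sex. Crh, the peptide that drives the stress axis, gave -0.082 ± 0.20 in females and -0.29 ± 0.20 in males, and its receptor Crhr1 gave -0.25 ± 0.17 and -0.20 ± 0.17. The peptide PACAP (Adcyap1) gave -0.58 ± 0.37 and 0.27 ± 0.36, and its receptor Adcyap1r1 gave 0.014 ± 0.12 and 0.069 ± 0.12. For the glucocorticoid receptor Nr3c1 the values were 0.051 ± 0.11 and 0.16 ± 0.11, and for its co-chaperone and target Fkbp5 -0.16 ± 0.13 and -0.0035 ± 0.12. The activity-induced factor Fos gave 0.043 ± 0.35 and -0.68 ± 0.36. Among peptides, Sst gave 0.20 ± 0.25 and -0.34 ± 0.25, Penk 0.17 ± 0.27 and -0.22 ± 0.27 and Pdyn -0.066 ± 0.10 and -0.22 ± 0.10. The estrogen receptor Esr1 gave -0.034 ± 0.27 and 0.11 ± 0.27, and aromatase (Cyp19a1) -0.33 ± 0.36 and -0.15 ± 0.34.

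**Figure D2:**
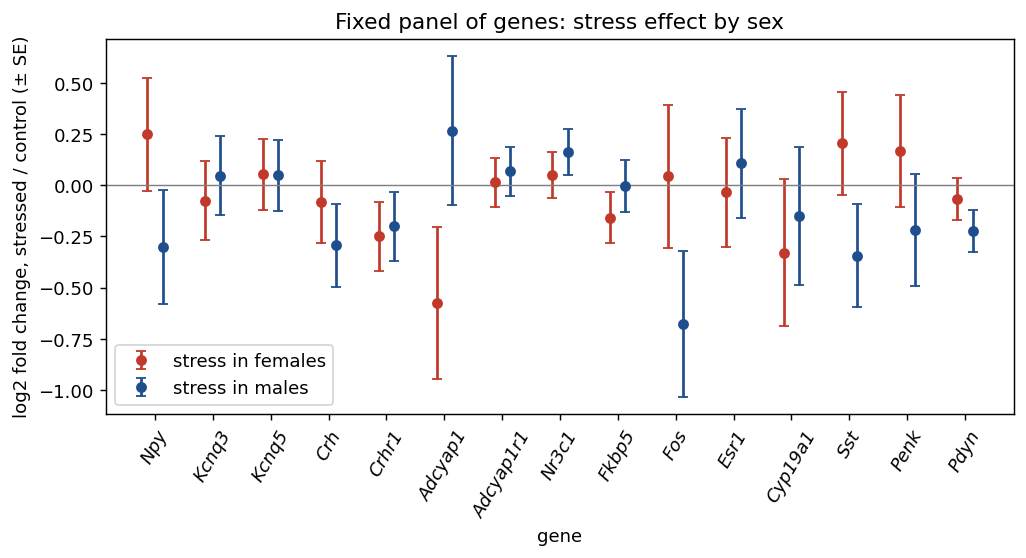
Log2 change with stress (± SE) of 15 genes fixed beforehand, in females and in males. None passed at an adjusted p under 0.05.

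In stressed against control females, no single gene passed, and the 1 list called with both correlation settings was the cold-inducible RNA-binding proteins, which bind mRNAs in cooled or stressed cells. Cirbp stood at 65.8 ± 7.09 CPM in controls and 82.9 ± 12.7 in stressed females (0.33 ± 0.13) and Rbm3 gave 0.27 ± 0.18. Camera called this list of 2 genes, with a median of 0.30 (adjusted p = 0.00161, and adjusted p = 0.0286 with an estimated correlation). In what follows a value marked estimated is the adjusted p with an estimated correlation. Neither gene passed over all genes, and 1 was higher adjusted over the list alone. Fry gave an adjusted p of 0.178 for the list, and the exact test of its score gave p = 0.00399 (adjusted p = 0.152). Its median was 0.15 in libraries numbered up to 5 and 0.47 in the others.

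Glucocorticoid target genes lay below 0 for 18 of 23 members (median -0.14, adjusted p = 0.00075, but 0.413 estimated). The cell-cycle inhibitor Cdkn1a gave -0.62 ± 0.20 and the transcription factor Zbtb16 -0.90 ± 0.30. Potassium channels other than KCNQ were below 0 for 28 of 37 (median -0.090, adjusted p = 0.00107, but 0.0963 estimated), as with Kcnc1 at -0.19 ± 0.089. The list of KCNQ, HCN and T-type calcium channels was below 0 for 10 of 12 (median -0.078, adjusted p = 0.0452, but 0.413 estimated), with the calcium channel Cacna1i at -0.081 ± 0.097. Neuropeptide receptors had a median of -0.075 (adjusted p = 0.0488, but 0.67 estimated), with the melanocortin receptor Mc4r at -0.22 ± 0.12. Clock genes had a median of 0.097 (adjusted p = 0.0288, but 0.318 estimated), with Dbp at 0.35 ± 0.17 and Arntl at -0.23 ± 0.11. Ribosomal protein transcripts were above 0 for 78 of 81 (median 0.13, adjusted p = 0.000868, but 0.925 estimated). Rpl4 gave 0.24 ± 0.16, and camera's direction turned without female stressed library 1 (adjusted p = 0.882, median still above 0) or 2 (adjusted p = 0.399) and the call was lost without female control library 10 (adjusted p = 0.0791).

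At its preset correlation camera also called 4 lists of cell-type markers in this comparison. Oligodendrocyte markers lay below 0 for 15 of 15 (median -0.17, adjusted p = 0.00161, but 0.67 estimated), with transferrin (Trf) at -0.44 ± 0.21 and the myelin glycoprotein Mag at -0.36 ± 0.24. Endothelial markers did so for 12 of 12 (median -0.12, adjusted p = 0.000868, but 0.412 estimated), with the junction protein Cdh5 at -0.36 ± 0.14. Markers of ependyma, the ciliated lining of the ventricles, were above 0 for 10 of 10 (median 0.22, adjusted p = 0.00682, but 0.67 estimated), with Cfap126 at 0.64 ± 0.36. Septal markers had a median of 0.28 (adjusted p = 0.0359, but 0.548 estimated), with the CRH receptor Crhr2 at 0.50 ± 0.23 (0.33 without female stressed library 8). Several medians differed in sign between the libraries numbered up to 5 and those from 6, at 0.40 and -0.25 for ribosomal proteins, -0.38 and 0.88 for septal markers and 0.072 and -0.31 for glucocorticoid targets, while oligodendrocyte markers gave -0.049 and -0.68.

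The exact test of list scores for stress in females passed for 0 of the 11 lists called by camera (adjusted p from 0.152 to 0.957), and for 0 with libraries exchanged only within the number sets (0.162 to 0.993). Single libraries are abbreviated from here on, as FS2 for female stressed library 2 and MC7 for male control library 7. For stress in females, of the 38 refits without a library the list call ended for the KCNQ list in 8 (FC1, FC6, FC10, FS3, FS6, FS7, FS8, FS9; adjusted p up to 0.149, median -0.065 without FC1) and neuropeptide receptors in 16 (up to 0.478, median -0.058 without FS2). It ended for clock genes in 3 (FC6, FC10, FS2; up to 0.163, median 0.055 without FS2) and oligodendrocyte markers in 3 (FC6, FS7, FS9; up to 0.155, median -0.076 without FS7). It ended for ependymal markers in 7 (FC1, FC2, FC3, FC6, FS7, FS8, FS9; up to 0.186, median 0.11 without FS7) and septal markers in 8 (FC1, FC2, FC3, FC6, FS6, FS7, FS8, FS9; up to 0.517, median 0.11 without FS7). Calls lost without the 5 libraries that stood apart were, with median and adjusted p, the KCNQ list (-0.086, 0.103), neuropeptide receptors (-0.023, 0.679) and clock genes (0.060, 0.116). Lost as well were endothelial markers (-0.042, 0.12) and ependymal markers (0.24, 0.0519). Medians of lists still called became -0.023 for other potassium channels, 0.051 for ribosomal proteins and -0.32 for oligodendrocyte markers. Without some library the median moved over 1.5 times for 10 of 11 lists, below 0.33 of its value for ribosomal proteins (0.024 without FS1 and -0.010 without FS2).

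The genes with the smallest p in females, none of which passed (adjusted p = 1 each), were Iqgap3 (0.89 ± 0.23), the iron reductase Cybrd1 (0.93 ± 0.25) and the selenoprotein gene Selenov (0.62 ± 0.17) on the higher side. On the lower side they were the endocytic adaptor Hip1 (-0.25 ± 0.072), the procollagen peptidase Adamts2 (-0.67 ± 0.20) and the clock-linked repressor Nfil3 (-0.46 ± 0.14). EdgeR, DESeq2 and voom called 0 genes in females. At unadjusted p under 0.05 edgeR had 307 (as many in 69 of 100 splits), where chance gives 815 in each comparison.

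In stressed against control males, 2 lists of basic cell functions had negative changes in nearly all members, while no single gene passed. Nuclear-encoded subunits of oxidative phosphorylation were below 0 for 73 of 74 (median -0.30), with Cox5a at 90.5 ± 14.1 CPM in controls and 72.8 ± 7.02 in stressed males (-0.31 ± 0.10) and the complex I subunit Ndufc1 at -0.41 ± 0.14. Cytosolic ribosomal proteins were below 0 for 79 of 81 (median -0.34), with Rps27l at -0.41 ± 0.15 and Rpl22l1 at -0.41 ± 0.16. Camera called both (adjusted p = 9.11e-20 and 9.11e-20), and both calls were lost with an estimated correlation (adjusted p = 0.452 each). The exact test of the scores gave p = 0.00495 for oxidative phosphorylation (adjusted p = 0.094) and p = 0.0373 for ribosomal proteins (adjusted p = 0.30). Both number sets gave negative medians, -0.31 and -0.28 for oxidative phosphorylation and -0.36 and -0.33 for ribosomal proteins. Without the 5 libraries that stood apart the medians were -0.20 and -0.22. These genes have short transcripts, and changes in males followed transcript length across all genes (Spearman 0.483), with a per-library length correlation of -0.0505 ± 0.218 (SD) in control and 0.173 ± 0.108 in stressed males (exact p = 0.0122).

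Immediate early genes, which respond to neuronal activity, were below 0 for 22 of 24 in males (median -0.27, adjusted p = 0.000432, but 0.59 estimated), with Fosl2 at -0.59 ± 0.24 beside Fos. Neuropeptides were below 0 for 24 of 26 (median -0.26, adjusted p = 0.0012, but 0.452 estimated), with Cartpt at -0.45 ± 0.17. Genes of glutamate signalling had a median of 0.069 (adjusted p = 0.0175, but 0.452 estimated), with the receptor Grm2 at 0.57 ± 0.24. GABA genes had a median of 0.080 (adjusted p = 0.0229, but 0.59 estimated), with Gabre at 0.72 ± 0.40. Other potassium channels had a median of 0.041 (adjusted p = 0.0298, but 0.452 estimated), with Kcnh5 at 0.59 ± 0.21. For neuropeptide receptors the median was 0.092 (adjusted p = 0.0498, but 0.76 estimated), with the opioid receptor Oprm1 at 0.67 ± 0.40. The sex-specific list was called as well (adjusted p = 0.0224, but 0.452 estimated), with Kdm5d at 0.34 ± 0.17.

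Choroid plexus markers were above 0 for 10 of 10 in stressed males (median 1.82, adjusted p = 4.85e-05, but 0.452 estimated), 0 of them over all genes and 9 higher adjusted over the list alone. This followed MS5, without which the adjusted p was 0.0768 and the median 0.23, and the thyroid hormone carrier Ttr (5.57 ± 1.19) and the potassium channel Kcnj13 (3.29 ± 0.78) were among its transcripts. Septal markers had a median of 0.40 (adjusted p = 0.00571, but 0.452 estimated), with Zic1 at 0.68 ± 0.29. Striatal markers were below 0 for 11 of 12 (median -0.27, adjusted p = 0.0498, but 0.799 estimated), with the dopamine receptor Drd2 at -0.34 ± 0.25. Endothelial markers had a median of 0.16 (adjusted p = 0.0298, but 0.59 estimated), with Flt1 at 0.30 ± 0.18. Fibroblast markers had a median of 0.24 (adjusted p = 0.045, but 0.651 estimated), with Igf2 at 0.74 ± 0.30, but at 0.066 without MS5.

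The exact test of list scores for stress in males passed for 0 of the 14 lists called by camera (adjusted p from 0.094 to 0.785), and for 0 with libraries exchanged only within the number sets (0.119 to 0.592). For stress in males, of the 38 refits without a library the list call ended for other potassium channels in 5 (MC6, MC7, MC9, MS7, MS8; adjusted p up to 0.218, median -0.0020 without MC7) and neuropeptide receptors in 28 (up to 0.431, median 0.069 without MS7). It ended for GABA genes in 6 (MC3, MC6, MC7, MC9, MS7, MS9; up to 0.136, median 0.045 without MC6) and the sex-specific list in 4 (MC7, MC8, MC9, MS4; up to 0.102, median 0.091 without MC7). It ended for endothelial markers in 9 (MC2, MC3, MC6, MC8, MC9, MS3, MS4, MS5, MS8; up to 0.236, median 0.13 without MC2) and fibroblast markers in 16 (up to 0.421, median 0.064 without MS5). It ended for striatal markers in 9 (FC7, MC1, MC3, MC4, MC5, MC6, MS6, MS7, MS8; up to 0.529, median -0.18 without MS8). The call also ended for glutamate genes without MC7 (adjusted p = 0.102, median 0.050). Calls lost without the 5 libraries that stood apart were, with median and adjusted p, neuropeptide receptors (0.067, 0.068), GABA genes (0.047, 0.068) and the sex-specific list (0.090, 0.068). Lost also were endothelial markers (0.12, 0.0901), fibroblast markers (0.18, 0.068) and striatal markers (-0.17, 0.0858). Among lists still called, the median became 0.094 for other potassium channels. Without some library the median moved over 1.5 times for 11 of 14 lists, below 0.33 of its value for other potassium channels (-0.0020 without MC7), fibroblast markers (0.064 without MS5), choroid plexus markers (0.23 without MS5) and striatal markers (-0.088 without MC4).

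Beside Ttr and Kcnj13, the smallest p values in males belonged to the kinase gene Mast4 (0.36 ± 0.088) on the higher side and to Bloc1s5, a gene of lysosome-related organelles (-0.40 ± 0.11), Hddc2 (-0.45 ± 0.13) and Gon7 (-0.47 ± 0.14) on the lower side. None passed (adjusted p = 0.575 for Ttr and 0.864 for the others). EdgeR, DESeq2 and voom called 0 genes, edgeR with 652 at unadjusted p under 0.05 (as many in 25 of 100).

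**Figure D3:**
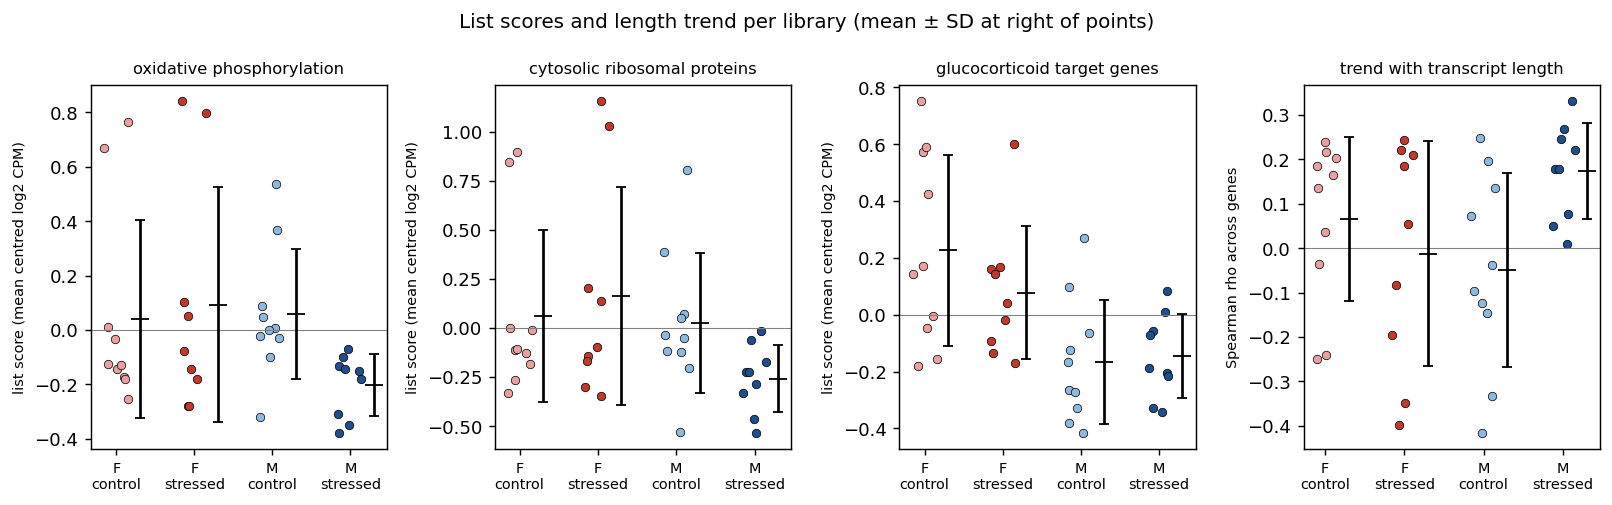
Scores of oxidative phosphorylation, ribosomal protein and glucocorticoid target genes per library, with the correlation of each library's expression with transcript length. Points are single libraries, with mean ± SD beside each group.

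In the test of whether stress effects differ between the sexes, camera at its preset correlation gave the smallest p to the same 2 lists of short transcripts. Ribosomal proteins were below 0 in the interaction for 78 of 81 (median -0.48, adjusted p = 7.28e-18) and oxidative phosphorylation for 73 of 74 (median -0.38, adjusted p = 2.28e-13), with Rpl14 at -0.61 ± 0.27 and Atp5c1 at -0.27 ± 0.12. Both calls were lost with an estimated correlation (adjusted p = 0.506 each). Within number sets the medians were -0.76 and -0.079 for ribosomal proteins and -0.60 and -0.017 for oxidative phosphorylation, and without the 5 libraries that stood apart, 4 of which are numbered up to 5, they were -0.28 and -0.22. Endothelial markers were above 0 for 12 of 12 (median 0.25, adjusted p = 0.000542, but 0.367 estimated), with Cdh5 at 0.55 ± 0.20. Other potassium channels had a median of 0.17 (adjusted p = 0.000579, but 0.143 estimated), with Kcnc1 at 0.30 ± 0.13. Genes of glutamate signalling had 0.19 (adjusted p = 0.0127, but 0.167 estimated), with the vesicular transporter Slc17a6 at 1.21 ± 0.53. Neuropeptide receptors had 0.17 (adjusted p = 0.0127, but 0.506 estimated), with Oprm1 at 1.06 ± 0.57. Oligodendrocyte precursor markers had 0.17 (adjusted p = 0.0476, but 0.327 estimated), with Gpr17 at 0.37 ± 0.19.

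At an adjusted p of 0.0463 each, camera also called neuropeptides (-0.26, Gnrh1 at -1.13 ± 0.46), immediate early genes (-0.31, Klf4 on the other side at 0.49 ± 0.25), striatal markers (-0.41, Gpr6 at -0.42 ± 0.30), glucocorticoid targets (0.10, Zbtb16 at 1.41 ± 0.43, 1 member higher adjusted over the list alone) and choroid plexus (1.7, 5 higher adjusted over the list alone). With an estimated correlation these gave adjusted p = 0.506, 0.786, 0.786, 0.686 and 0.686. Single genes nearest to an interaction were Mast4 (0.59 ± 0.13, adjusted p = 0.524), the actin regulator Wasf3 (0.58 ± 0.16) and Cpne9 (1.99 ± 0.55) on the higher side and Hddc2 (-0.64 ± 0.18), Bloc1s5 (-0.52 ± 0.15) and the mitochondrial gene Mterf4 (-0.46 ± 0.14) on the lower side, none of which passed. EdgeR, DESeq2 and voom called 0 genes for the interaction, edgeR with 731 at unadjusted p under 0.05 (as many in 29 of 100). Across genes, stress effects in females and males correlated at -0.197 (Pearson), with the same sign for 37.2%. Both followed transcript length (-0.289 and 0.483), a trend not separated from stress.

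For the interaction, of the 38 refits without a library the list call ended for glucocorticoid targets in 20 (adjusted p up to 0.199, median 0.079 without FC1) and immediate early genes in 19 (up to 0.288, median -0.24 without FS6). It ended for neuropeptides in 13 (up to 0.13, median -0.15 without MC7) and oligodendrocyte precursors in 24 (up to 0.13, median 0.12 without FC6). It ended for choroid plexus markers in 19 (up to 0.567, median 0.12 without MS5) and striatal markers in 18 (up to 0.253, median -0.34 without MS8). The call also ended for neuropeptide receptors without FC10 or MS7 (adjusted p = 0.0656 and 0.0752, medians 0.12 and 0.11). Calls lost without the 5 libraries that stood apart were, with median and adjusted p, neuropeptide receptors (0.085, 0.0938) and oligodendrocyte precursors (0.17, 0.102). Lost too were choroid plexus markers (1.57, 0.106) and striatal markers (-0.24, 0.0938). Among lists still called, the median became 0.11 for glutamate genes. Without some library the median moved over 1.5 times for 10 of 12 lists, below 0.33 of its value for glutamate genes (0.041 without MS4) and choroid plexus markers (0.12 without MS5).

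Averaged over the sexes, camera called 13 lists for stress while no gene passed. Septal markers had a median of 0.32 (adjusted p = 2.60e-05, but 0.354 estimated), with Zic1 at 0.49 ± 0.21. Oligodendrocyte markers lay below 0 for 15 of 15 (median -0.17, adjusted p = 0.0135, but 0.901 estimated), with Trf at -0.29 ± 0.15. Oxidative phosphorylation had -0.097 (adjusted p = 1.21e-11, but 0.789 estimated) and ribosomal proteins -0.092 (adjusted p = 1.89e-07, but 0.888 estimated). Immediate early genes had -0.11 (adjusted p = 0.000175, but 0.789 estimated) and neuropeptides -0.094 (adjusted p = 0.00292, but 0.507 estimated), with Fosl2 at -0.46 ± 0.17 and Cartpt at -0.26 ± 0.12. Cold-inducible proteins had 0.17 (adjusted p = 0.0207, but 0.324 estimated), glucocorticoid targets -0.082 (adjusted p = 0.0216, but 0.813 estimated) and clock genes 0.068 (adjusted p = 0.0296, but 0.507 estimated).

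Choroid plexus markers had an averaged median of 0.97 (adjusted p = 5.13e-05, but 0.507 estimated, 10 higher adjusted over the list alone, but 0.12 without MS5), ependymal markers 0.14 (adjusted p = 0.0135, but 0.888 estimated), fibroblast markers 0.095 (adjusted p = 0.0207, but 0.789 estimated) and GABA genes 0.046 (adjusted p = 0.0191, but 0.789 estimated). The smallest p values were those of Ttr (2.9 ± 0.78, but 0.48 without MS5), Cybrd1 (0.57 ± 0.17) and the glial factor Sox9 (0.21 ± 0.066), and of the fatty acid carrier Fabp7 (-0.30 ± 0.085), Klhl40 (-0.62 ± 0.18) and the crystallin gene Crybb3 (-0.67 ± 0.21) on the lower side, and none passed (adjusted p = 1.0 each). EdgeR called 0 genes for the average, with 238 at an unadjusted p under 0.05, and DESeq2 and voom also called 0. For the average, of the 38 refits without a library the list call ended for glucocorticoid targets in 10 (adjusted p up to 0.285, median -0.051 without FC7) and GABA genes in 7 (FC5, FC6, FC9, MC3, MC6, MC7, FS4; up to 0.105, median 0.028 without FC6). It ended for clock genes in 7 (FC8, FC10, MC3, MC5, MC9, FS2, MS3; up to 0.197, median 0.069 without FS2) and cold-inducible proteins in 5 (MC4, MC5, MC10, FS2, MS1; up to 0.0767, median 0.17 without FS2). It ended for oligodendrocyte markers in 11 (up to 0.106, median -0.12 without FS7) and fibroblast markers in 11 (up to 0.279, median 0.026 without MS5). It ended for ependymal markers in 12 (up to 0.132, median 0.061 without MS8). Calls lost without the 5 libraries that stood apart were, with median and adjusted p, clock genes (0.047, 0.329) and cold-inducible proteins (0.16, 0.0766). The rest were fibroblast markers (0.067, 0.0999) and ependymal markers (0.083, 0.115). Without some library the median moved over 1.5 times for 10 of 13 lists, below 0.33 of its value for fibroblast markers (0.026 without MS5) and choroid plexus markers (0.12 without MS5).

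**Figure D4:**
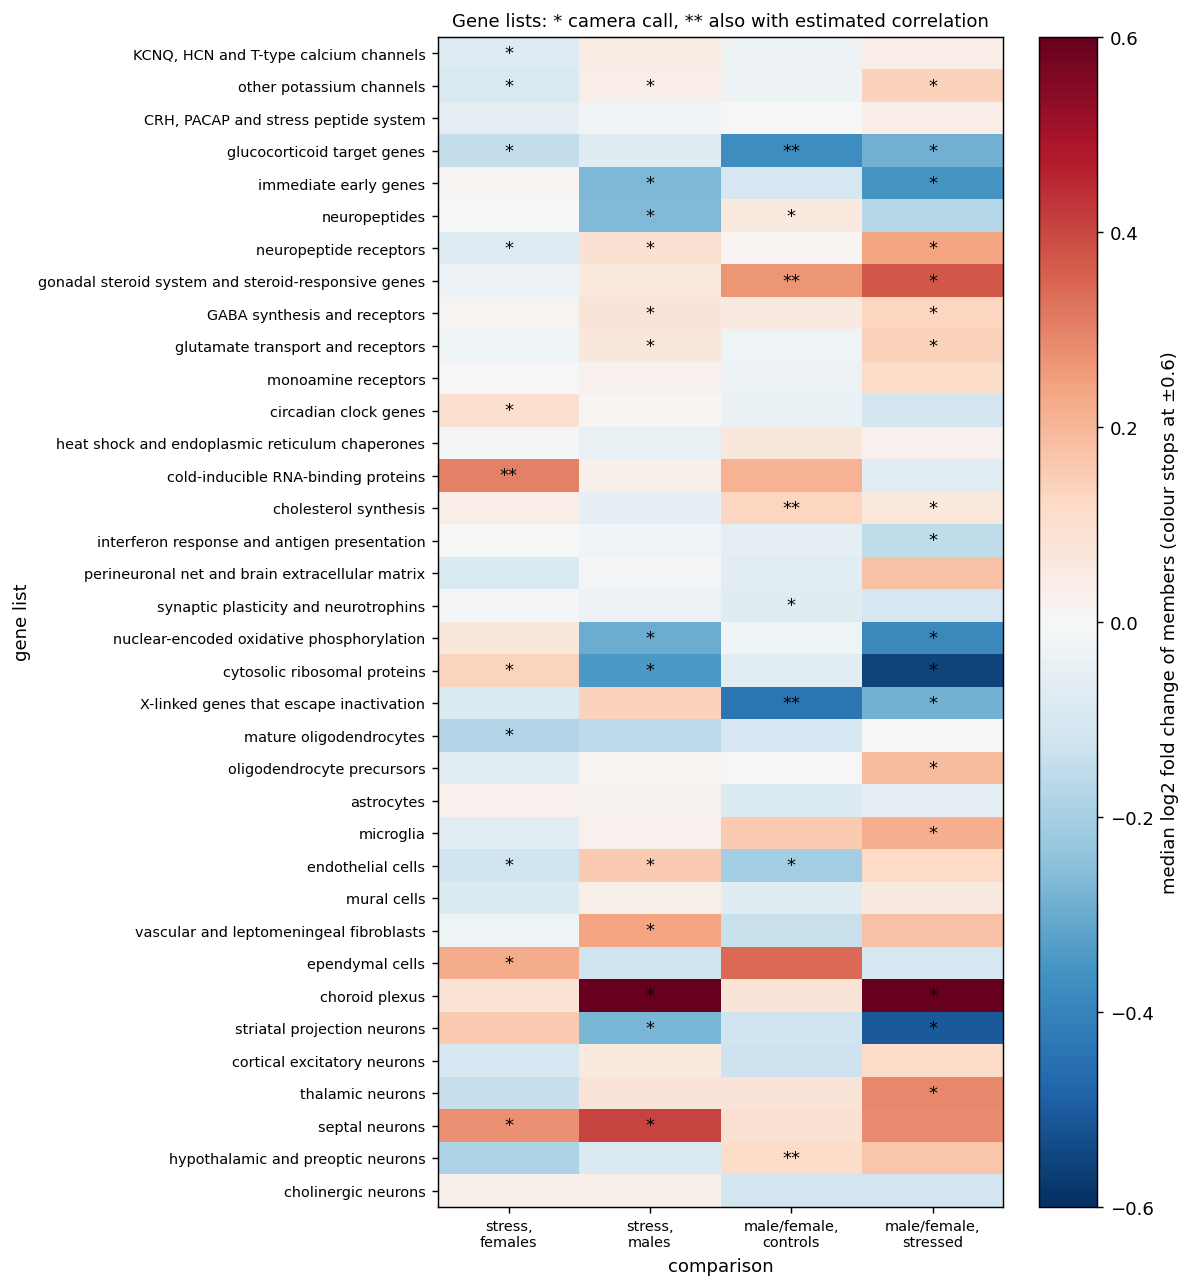
Median log2 change of each gene list under stress in each sex and between the sexes in controls and stressed mice. 1 star marks lists called by camera at its preset correlation and 2 stars those also called with an estimated correlation.

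Between male and female controls, a small set of genes outside the known sex-specific list differed. Cckar, a cholecystokinin receptor on chromosome 5 (53698485 to 53707704), stood at 7.14 ± 3.42 CPM in males and 2.21 ± 0.912 in females (1.69 ± 0.26, adjusted p = 0.000273). Sytl4, an X-linked gene of vesicle release (133936385 to 133981821), stood at 31.9 ± 11.3 and 11.4 ± 3.27 (1.49 ± 0.23, adjusted p = 0.000273). Hcrtr1, an orexin receptor on chromosome 4 (130130217 to 130139594), stood at 6.07 ± 2.89 and 2.38 ± 0.942 (1.34 ± 0.26, adjusted p = 0.0164). Kdm5c, an X-linked demethylase that escapes inactivation (152233198 to 152279102), fell in males (-0.49 ± 0.072, adjusted p = 9.99e-05), as did Jpx, an X-linked non-coding RNA that activates Xist (-0.57 ± 0.12, adjusted p = 0.049). The Y-linked gene Uba1y stood at 0.837 ± 0.545 CPM in males and 0.0030 in females. Xdh, the xanthine dehydrogenase, came next without passing (-1.17 ± 0.25, adjusted p = 0.0524).

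Within number sets Cckar gave 1.91 ± 0.31 and 1.56 ± 0.35, Sytl4 1.36 ± 0.24 and 1.61 ± 0.30, Hcrtr1 1.2 ± 0.30 and 1.42 ± 0.33 and Kdm5c -0.49 ± 0.11 and -0.48 ± 0.098. Jpx gave -0.76 ± 0.16 and -0.35 ± 0.18 there and lost its call in 28 of the 38 refits without a library, with changes of -0.51 to -0.59 in those (adjusted p up to 0.172, without FC4). Hcrtr1 lost its call without FC2 (1.27, adjusted p = 0.0531), MC8 (1.26, adjusted p = 0.0556) or MC9 (1.15, adjusted p = 0.0877), and its adjusted p was 0.0946 without the 5 libraries that stood apart. EdgeR called 8 genes higher and 3 lower, 6 of them outside the sex-specific list, with 675 at an unadjusted p under 0.05, and DESeq2 called 21 and voom 30.

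Glucocorticoid target genes were below 0 in male against female controls for 20 of 23 members (median -0.37). The list was called lower by camera (adjusted p = 1.13e-13, and 0.0147 estimated) and by fry (adjusted p = 0.0191). The permutation test of its score gave p = 0.00719 (adjusted p = 0.0911). No member passed over all genes and 8 were lower adjusted over the list alone, among them the phagocytic receptor Mertk (-0.49 ± 0.11) and Zbtb16 (-1.28 ± 0.30). The median was -0.17 in libraries numbered up to 5, -0.41 in the others and -0.21 without the 5 libraries that stood apart. Endothelial markers were below 0 for 11 of 12 (median -0.21, adjusted p = 2.20e-05, but 0.143 estimated), 0 over all genes and 3 adjusted over the list alone, with the glucose transporter Slc2a1 at -0.37 ± 0.12.

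The list of gonadal steroid genes was called higher in males, with 13 of 16 above 0 (median 0.26, adjusted p = 3.67e-11, and 0.040 estimated). Cckar and Sytl4 passed over all genes, 4 members were higher adjusted over the list alone, and aromatase (Cyp19a1) did not pass (1.28 ± 0.34, adjusted p = 0.294). Genes of cholesterol synthesis had values above 0 in 23 of 23 members and were called as a list (median 0.13, adjusted p = 1.36e-06, and 5.54e-05 estimated), 0 passing over all genes and 0 adjusted over the list alone, with Nsdhl at 0.21 ± 0.079. X-linked genes that escape inactivation were below 0 for 6 of 6 (median -0.44, adjusted p = 2.89e-15, and 0.000153 estimated), 1 over all genes and 5 adjusted over the list alone. The list of hypothalamic and preoptic markers was called higher (median 0.11, adjusted p = 0.000127, and 0.0486 estimated), 0 over all genes and 2 adjusted over the list alone, with vasopressin (Avp) at 1.07 ± 0.30 and galanin (Gal) at 0.97 ± 0.22. Their median was -0.040 and 0.40 in the number sets, and fry gave an adjusted p of 0.0534. The sex-specific list was called with both correlations (adjusted p = 1.57e-37 and 1.64e-07). Plasticity genes had a median of -0.071 (adjusted p = 0.0152, but 0.316 estimated), with Shank2 at -0.30 ± 0.089, and neuropeptides 0.061 (adjusted p = 0.0176, but 0.411 estimated), with the granin Chgb at 0.29 ± 0.093. The permutation test of list scores between the sexes in controls passed for the sex-specific list (adjusted p = 0.00038) and escape genes (0.030). It did not pass for the other 7 lists called by camera (adjusted p from 0.0911 to 0.637, 0.10 for cholesterol synthesis, 0.105 for gonadal steroid genes). Within the number sets these 2 passed (adjusted p = 0.0012 and 0.0204) and the others did not (from 0.0898 to 0.579). Between the sexes in controls, of the 38 refits without a library the list call ended for neuropeptides in 5 (FC2, FC3, FC4, MC3, MC7; adjusted p up to 0.164, median 0.036 without MC7). Calls were also lost for plasticity genes without FC1 or MC7 (adjusted p = 0.228 and 0.0917, medians -0.046 and -0.014). The call lost without the 5 libraries that stood apart was, with median and adjusted p, plasticity genes (-0.056, 0.48). Among lists still called, the median became 0.17 for neuropeptides. Without some library the median moved over 1.5 times for 5 of 9 lists, below 0.33 of its value for neuropeptides (0.016 without FC2 and 0.014 without MC3), plasticity genes (-0.014 without MC7 and -0.016 without MC9) and hypothalamic markers (0.033 without FC8 and 0.033 without MC9).

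In stressed mice Cckar, Sytl4 and Hcrtr1 again separated the sexes, with Greb1, Gal and Ppp1r3e beside them. Cckar stood at 6.25 ± 3.37 CPM in males and 1.62 ± 0.384 in females (1.94 ± 0.28, adjusted p = 9.29e-05), Sytl4 at 28.8 ± 9.25 and 11 ± 6.01 (1.38 ± 0.24, adjusted p = 0.00322) and Hcrtr1 at 5.67 ± 2.36 and 2.24 ± 1.01 (1.33 ± 0.28, adjusted p = 0.0359). Greb1, an estrogen-induced gene on chromosome 12 (16670615 to 16801394), stood at 26.8 ± 19.2 and 6.11 ± 3.35 (2.12 ± 0.42, adjusted p = 0.0167). Gal, a peptide on chromosome 19 (3409915 to 3414544), stood at 10.8 ± 5.16 and 5.14 ± 1.21 (1.08 ± 0.23, adjusted p = 0.0433), and the glycogen phosphatase subunit Ppp1r3e on chromosome 14 at 9.06 ± 0.962 and 6.22 ± 0.649 (0.54 ± 0.099, adjusted p = 0.00496). Uba1y stood at 1.01 ± 0.449 CPM in males and at 0 in females. Ttr (6.66 ± 1.32, adjusted p = 0.0167) and Kcnj13 (3.97 ± 0.86, adjusted p = 0.0456) passed through MS5. Without that library Ttr gave 1.82, adjusted p = 0.462 and Kcnj13 0.95, adjusted p = 0.535, and with marker scores that include choroid plexus as covariates Ttr gave -0.52. Lower in males outside the sex-specific list, none passed, with Rgcc at -0.58 ± 0.13 (adjusted p = 0.108), Tfcp2l1 at -0.75 ± 0.19 and Fcor at -0.87 ± 0.22. Npy gave -0.94 ± 0.29 (adjusted p = 0.379) and -0.27 ± 0.11 without the 5 libraries that stood apart.

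**Figure D5:**
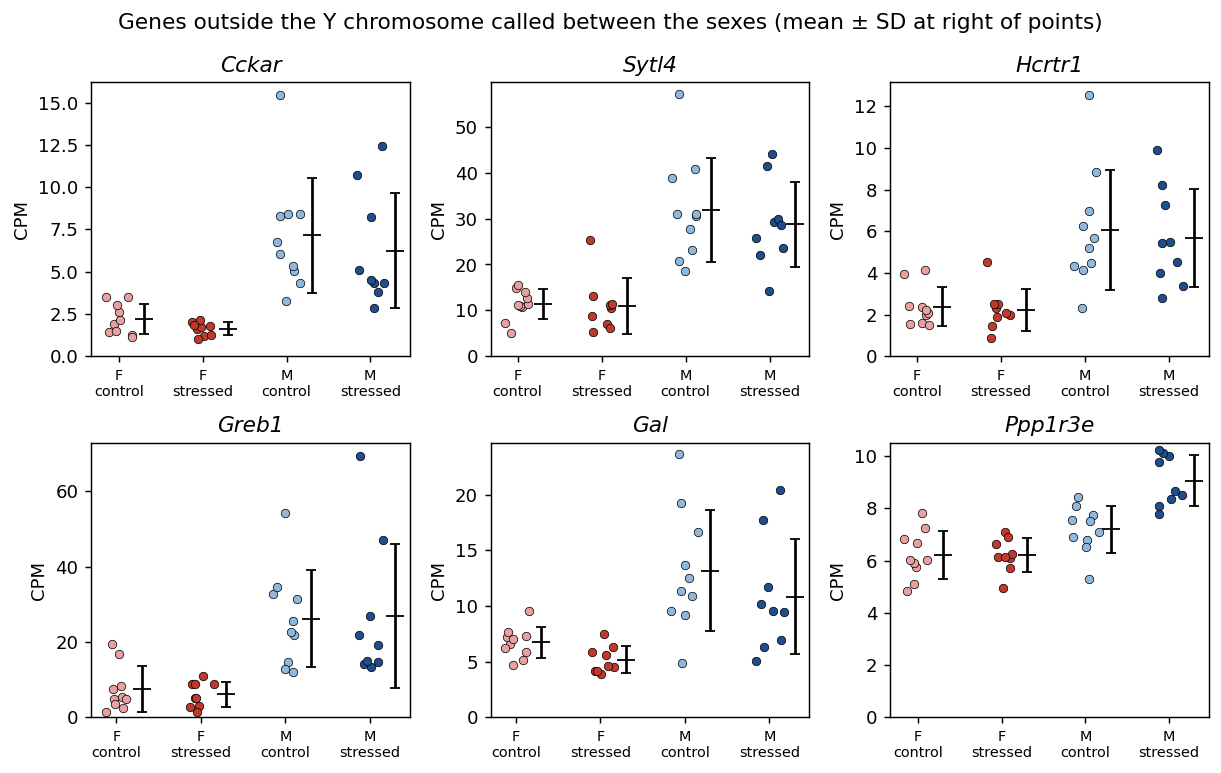
CPM per library of 6 genes called between the sexes outside the Y chromosome, with mean ± SD per group. Values of all 38 libraries are shown.

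Hcrtr1 lost its call in stressed mice in 10 of the 38 refits without a library, with changes of 1.2 to 1.36 there (adjusted p up to 0.138, without MS7), and Gal in 15, with 0.91 to 1.11 (up to 0.227, without MS8). Greb1 lost it without FS3 (2.04, adjusted p = 0.0541) or MS7 (1.81, adjusted p = 0.0875). Ttr lost it also without female stressed libraries 3, 4 or 9 (adjusted p = 0.0541, 0.0529 and 0.0567) at 6.54 to 6.57, and Kcnj13 in 24 refits beside that without MS5 at 3.85 to 4.25, so these changes shrank only without that library. Without the 5 libraries that stood apart the calls of Hcrtr1 (1.2 ± 0.29, adjusted p = 0.197), Greb1 (1.9 ± 0.43, 0.102), Ttr (6.53 ± 1.6, 0.229) and Kcnj13 (3.72 ± 0.91, 0.228) ended. Within number sets Cckar gave 1.82 ± 0.31 and 2.06 ± 0.40, Sytl4 1.68 ± 0.24 and 1.2 ± 0.33, Hcrtr1 1.32 ± 0.30 and 1.36 ± 0.37, Greb1 2.17 ± 0.43 and 2.11 ± 0.61, Gal 0.70 ± 0.29 and 1.44 ± 0.30 and Ppp1r3e 0.54 ± 0.14 and 0.55 ± 0.16. EdgeR called 13 genes higher and 1 lower, 9 of them outside the sex-specific list, with 1811 at an unadjusted p under 0.05, and DESeq2 called 24 and voom 21.

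Gene groups between the sexes in stressed mice held with an estimated correlation only for the sex-specific list (adjusted p = 8.84e-26 and 7.73e-06). Ribosomal proteins were below 0 in males for 80 of 81 (median -0.56, adjusted p = 4.07e-27, but 0.257 estimated), 0 over all genes and 65 adjusted over the list alone, with Rpl38 at -0.69 ± 0.21. Oxidative phosphorylation did so for 69 of 74 (median -0.39, adjusted p = 3.94e-14, but 0.307 estimated), with Cox7a2 at -0.44 ± 0.15. Without the 5 libraries that stood apart these medians were -0.16 and -0.080, and the effect followed transcript length across genes (Spearman 0.40). Gonadal steroid genes had 12 of 16 above 0 (median 0.37, adjusted p = 6.18e-08, but 0.165 estimated), 3 higher over all genes and 7 adjusted over the list alone. Striatal markers were below 0 for 12 of 12 (median -0.51, adjusted p = 3.99e-05, but 0.327 estimated), with the phosphatase inhibitor Ppp1r1b at -0.97 ± 0.34. Immediate early genes were below 0 for 24 of 24 (median -0.35, adjusted p = 8.44e-05, but 0.327 estimated), with Fosb at -0.70 ± 0.26. Neuropeptide receptors had a median of 0.23 (adjusted p = 5.33e-05, but 0.257 estimated), 2 higher over all genes and 2 adjusted over the list alone. X-linked escape genes had -0.29 (adjusted p = 0.000134, but 0.165 estimated), with Pbdc1 at -0.39 ± 0.10 and Kdm5c at -0.28 ± 0.075.

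Glucocorticoid targets in stressed males against stressed females had a median of -0.29 (adjusted p = 0.00413, but 0.327 estimated), with the metallothioneins Mt1 at -0.95 ± 0.30 and Mt2 at -0.94 ± 0.25 (-0.61 and -0.63 without FS2). Glutamate genes had 0.14 (adjusted p = 0.0261, but 0.167 estimated), with Grik1 at 0.77 ± 0.19 and Slc17a6 at 1.44 ± 0.39. Cholesterol synthesis had 0.062 (adjusted p = 0.026, but 0.16 estimated). Other potassium channels had 0.14 (adjusted p = 0.013, but 0.177 estimated) and GABA genes 0.13 (adjusted p = 0.0261, but 0.429 estimated), with members such as Kcnh3 (-0.50 ± 0.17) and Gabrd (-0.53 ± 0.23) on the lower side. Interferon genes had -0.15 (adjusted p = 0.028, but 0.486 estimated), with Ifit3 at -0.82 ± 0.25.

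Choroid plexus markers had 1.97 in this comparison (adjusted p = 0.00351, but 0.328 estimated, and 0.246, with a median of 0.20, without MS5), 2 higher over all genes and 7 adjusted over the list alone. Microglial markers had 0.22 (adjusted p = 0.0118, but 0.486 estimated), with the fractalkine receptor Cx3cr1 at 0.46 ± 0.23. Thalamic markers had 0.29 (adjusted p = 0.028, but 0.302 estimated) and oligodendrocyte precursors 0.19 (adjusted p = 0.0293, but 0.167 estimated).

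The exact test of list scores between the sexes in stressed mice passed for gonadal steroid genes (adjusted p = 0.0203), glutamate genes (0.0117), cholesterol synthesis (0.0207) and the sex-specific list (0.00156). It did not pass for the other 14 lists called by camera (adjusted p from 0.0519 to 0.656). Within the number sets these 4 passed (adjusted p = 0.00862, 0.00969, 0.0146 and 0.00431), as did neuropeptide receptors (0.00969), thalamic markers (0.0172), striatal markers (0.0351), ribosomal proteins (0.0388), oligodendrocyte precursors (0.0388) and other potassium channels (0.0391), and the other 8 did not (from 0.053 to 0.635). Between the sexes in stressed mice, of the 38 refits without a library the list call ended for interferon genes in 5 (FS6, FS7, FS9, MS1, MS7; adjusted p up to 0.671, median 0.017 without FS9) and oligodendrocyte precursors in 3 (FS8, FS9, MS5; up to 0.0868, median 0.18 without MS5). It ended for thalamic markers in 5 (FS4, FS5, FS6, FS9, MS8; up to 0.224, median 0.15 without MS8). Calls were also lost for other potassium channels without FS6 (adjusted p = 0.0547, median 0.11) and GABA genes without FS8 or MS9 (adjusted p = 0.0726 and 0.0523, medians 0.096 and 0.10). It also ended for glutamate genes without FS6 or FS8 (adjusted p = 0.0547 and 0.0553, medians 0.14 and 0.11) and cholesterol synthesis without FS7 or FS9 (adjusted p = 0.0534 and 0.0613, medians 0.057 and 0.070). The call also ended for microglial markers without FS8 or MS5 (adjusted p = 0.0954 and 0.0879, medians 0.14 and 0.13). The call lost without the 5 libraries that stood apart was, with median and adjusted p, GABA genes (0.069, 0.0726). Medians of lists still called became -0.17 for glucocorticoid targets, 0.13 for neuropeptide receptors, 0.23 for gonadal steroid genes, 0.056 for glutamate genes and -0.23 for striatal markers. Without some library the median moved over 1.5 times for 9 of 18 lists, below 0.33 of its value for glutamate genes (0.0048 without MS4), interferon genes (0.017 without FS9) and choroid plexus markers (0.20 without MS5).

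Sex effects in controls and in stressed mice, with the sex-specific list left out, had a Pearson correlation of 0.252 over 16304 genes and the same sign for 53.4%. Lists that camera called in no comparison were monoamine receptors (smallest adjusted p over the comparisons 0.127), chaperones (0.291), CRH and PACAP peptides (0.299), perineuronal net genes (0.10), astrocytes (0.0601), mural cells (0.291), cholinergic neurons (0.358) and cortical neurons (0.54). The single tested blood gene gave a median of -0.18 for stress in females and -0.19 in males.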

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

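Chosen after seeing the results were the tests without the 5 libraries that stood apart, the split by direction of the genes that differ between the number sets, the test among genes that still pass the filter after thinning, the score test of glucocorticoid targets between the sexes, the transcript length correlation of each library, and the splits and score tests within the number sets. The tests of a stress effect in males and of a sex difference in controls were changed after their values were seen, from unadjusted p to p adjusted over all lists, and both are now left open. The readings of other tests were also changed after their values were seen. The endothelial test, first read as arguing against, is now left open, as libraries that stood apart enter its slope. The clock gene test was first read as arguing against a difference in time of collection and is now left open, because its members go both ways. The thinning test passed its bound narrowly at 68.1%, was first read as arguing against depth and was later left open, because the interval around that value reaches below the bound.

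Values far from the rest of their group were looked for in 178 groups of values, where chance alone gives 9, and 17 were found. MS5 held 4 of them, with Ttr at 2878 CPM (41.1 in the next library) and Kcnj13 at 34.5 (0.835). The others were a choroid plexus score of 4.61 (0.821) and an oligodendrocyte precursor score of 0.359 (0.156). FS8 held 3, Crhr1 at 15.3 CPM (9.42), Sytl4 at 25.4 (13.1) and Hcrtr1 at 4.55 (2.52). MC9 held Cckar at 15.5 (8.42) and Ttr at 27.5 (11.3). Other single values were the total of 84.8 M counts in MC1 (40.6) and Crh at 39.3 CPM in FC8 (27.0). Fos stood at 56.4 in FS6 (25.7), Cyp19a1 at 4.83 in FC10 (2.50) and Kdm5d at 68.7 in MS4 (52.5). Low scores were those of choroid plexus in MC3 (-1.83, next -0.60) and of hypothalamic neurons in MC4 (-0.67, next 0.10). A high score was that of thalamic markers in MS8 (1.07, next 0.26).

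The stress effect differed between the sexes for 12 gene lists in camera's test of the interaction at its preset correlation, and for none with an estimated correlation, where adjusted p ran from 0.143 to 0.786. Medians of males minus females were -0.48 for ribosomal proteins, -0.38 for oxidative phosphorylation, 0.25 for endothelial markers, 0.17 for other potassium channels, 0.17 for neuropeptide receptors, 0.19 for glutamate genes and -0.26 for neuropeptides. They were 1.7 for choroid plexus (0.12 without MS5), 0.10 for glucocorticoid targets and -0.31 for immediate early genes. Striatal markers had -0.41 and oligodendrocyte precursors 0.17.

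Ribosomal protein and oxidative phosphorylation transcripts, picked from this comparison for their result, had negative changes in stressed males, with an exact p of 0.0162 for the combined score but score p adjusted over all lists of 0.30 and 0.094 for the 2 lists in turn (0.158 and 0.119 with libraries exchanged only within the number sets), and an adjusted camera p of 0.452 with an estimated correlation, so a stress effect stays open as a hypothesis found and tested on the same data. Of 1000 gene sets matched on transcript length and expression, 0 had a median as low as the -0.31 of the members. The sets' median was -0.22, so other short transcripts shared much of the shift. Random sets ignore correlation between members, so length stays open. Without the 5 libraries that stood apart the members' median was -0.209, between the bounds set for that explanation, and their part stays open. Without MC3 the score difference was -0.20 (exact p = 0.0274). RNA quality may contribute, since the length correlation of libraries differed between male groups as well, and the labels give no measure of it.

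Libraries numbered up to 5 and from 6 differed for 495 genes by at least 2-fold, and the labels name no batch. A trend with transcript length was argued against, at a correlation of 0.0246 across genes. Reads shared between near-identical gene copies may explain 13 of the 147 genes lower from 6. Genes with mostly shared sequence were 4.08 times as frequent there as among other genes. Shared reads are argued against for the 348 higher ones at 0.647 times, with 1.65 times over all. After thinning to the lowest total 68.1% of the genes stayed 2-fold different, which leaves depth open for the whole set, while among those still tested 93.6% did (lower 95% bound 90.6), which argues against depth for them. No biological explanation was tested, as no group follows these numbers.

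Glucocorticoid target genes had medians below 0 in male against female controls in both number sets (-0.17 and -0.41), and the permutation p of the score was 0.00719, but 0.0911 adjusted over all lists (0.0898 within the number sets). A smaller share of endothelial cells stays open. The median was -0.444 with the endothelial score as a covariate and -0.37 without, but libraries that stood apart enter the slope. A different time of collection stays open, since the other clock genes had a median of 0.0157 with 9 members up and 7 down. Without the 5 libraries that stood apart the median was -0.212, which neither keeps nor loses most of the shift, and their part stays open. A sex difference in unstressed mice also stays open at the adjusted 0.0911, as a hypothesis found and tested on the same data.

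Libraries were also split at random into groups of the same sizes, 100 splits with the real one, which ignored the number sets. For genes between the sexes chance was excluded, since the real split alone gave as many (1 of 100) in controls, with 11 genes against at most 1 in another split, and in stressed mice (1 of 100), with 14 against at most 0. For stress the real counts of 0 were reached by 100 of 100 splits in females, males, the interaction and the average, as any split must, so these splits test nothing there, and other splits called up to 3599, 3308, 588 and 1861 genes. Splits that call so many genes point to a structure of the libraries that does not follow stress. For the number of lists called, chance could not be excluded in any comparison. As many lists came from 15 splits for stress in females (11 real, 17 highest other), 17 in males (14 and 20), 21 for the interaction (12 and 16), 9 for the average (13 and 18), 45 between the sexes in controls (9 and 18) and 5 in stressed mice (18 and 22).

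Splits within the number sets, again 100, were chosen after these results were seen. Between the sexes the real split gave 11 genes in controls and 14 in stressed mice, against at most 1. Xist and Y-linked genes are again among them, so these splits do not judge the other genes either. Other splits for stress called up to 3574 genes in females, and at most 1 in males, the interaction and the average. As many lists came from 21 splits in females (11 real, 16 highest other), 9 in males (14 and 19), 20 for the interaction (12 and 17), 10 for the average (13 and 15) and 39 between the sexes in controls (9 and 19), so chance was not excluded for these counts. In stressed mice 4 splits gave as many (18 and 19), which argues against chance only narrowly, as 5 did so when the sets were ignored. These counts do not judge single lists, as in controls the score of the sex-specific list gave p = 1e-05, the smallest the resamples can give (adjusted p = 0.00038).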

How the results depend on the processing

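Settings that left out male stressed library 5 or the 5 libraries that stood apart, those that used a single number set, and the refits of the list test with the number set term or without a library were chosen after seeing the data, and the other settings were planned. Every setting written down beforehand was run. In 53 refits beside the planned design, 0 genes were called for stress in females, in males, in the interaction and in the average. Genes called outside the sex-linked lists between the sexes kept their direction in these settings except Ttr, which changed sign in stressed mice with marker scores, a choroid plexus score among them, as covariates. Of 15 settings, calls in controls ended in 1 for Cckar, 1 for Sytl4, 3 for Hcrtr1, 2 for Kdm5c and 6 for Jpx. In stressed mice they ended in 1 for Cckar, 1 for Sytl4, 4 for Hcrtr1, 4 for Gal, 5 for Ppp1r3e and 6 for Greb1, in 12 of the 14 that could test Kcnj13, and in 13 for Ttr. Of the values of single genes, 3816 were on the same side of the threshold with the same sign, 59 no longer passed, 39 passed only in the alternative and 172 changed sign, all but Ttr among genes that did not pass in the planned test. For the 77 lists already called, the counts were 3136, 626 no longer passing and 11 with camera's direction turned, and lists called only in an alternative are not in them. Libraries of different groups that share a number were no closer than others of their number set, with a median correlation of 0.235 over 55 pairs against 0.238, and 9 of 38 libraries had their own number as best match. With the replicate number as a block, edgeR called 13 genes between the sexes in controls and 14 in stressed mice. Depth limits the genes near the filter, since a single count was worth 0.11 CPM in the shallowest library.

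Without 1 library at a time, the count of genes ran from 9 to 15 between the sexes in controls and from 9 to 15 in stressed mice, and was 0 to 0 for the stress comparisons. Lists called ran from 7 to 14 for stress in females, 8 to 14 in males, 6 to 13 for the interaction, 8 to 14 for the average, 8 to 15 between the sexes in controls and 14 to 21 in stressed mice. The adjusted p of ribosomal proteins for stress in females ran from 5.91e-14 without FC6 to 0.882 without FS1. Camera's direction turned in 2 of these refits, the median in 1.

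The planned count of 11 genes between the sexes in controls became 21 with DESeq2, 30 with voom, 42 with surrogate variables, 18 at an adjusted p under 0.10, 34 without the 5 libraries and with the number set term, 30 when male stressed library 5 was left out too, and 7 with numbers up to 5 alone. The 14 in stressed mice became 24 with DESeq2, 8 with numbers up to 5 alone and 6 with numbers from 6 alone. Fewer samples are part of the last counts. In simulated counts DESeq2 made more false calls than edgeR in these comparisons, 10.5% and 12.3% against 1.71% and 5.74%, which may add to its counts of 21 and 24, and for the rest the cause was not tested.

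Lists called were 11 for stress in females, 14 in males, 12 in the interaction, 13 in the average, 9 between the sexes in controls and 18 in stressed mice. An estimated correlation left 1, 0, 0, 0, 6 and 1 of them, which follows from its construction, since correlated members count as less evidence. Fry called 0, 0, 0, 0, 5 and 3. Leaving out the 5 libraries gave 7 for stress in females and 8 in males, 7 in females with the number set term, and 7 in females and 9 in males when male stressed library 5 was left out too. Marker scores as covariates gave 7 for the average. Between the sexes in controls the count was 14 with the number set term, 14 when male stressed library 5 was left out as well, 14 with numbers up to 5 alone and 17 with numbers from 6 alone. In stressed mice it was 10 with numbers up to 5 alone. For these the cause was not tested.

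Values of the other sign follow by setting, as log2 changes for genes and as camera's adjusted p for lists, whose direction is camera's. Fitted values of Ddx3y and Xist within the sex that lacks them rest on at most 26 counts. The cause was not tested for any of them.

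DESeq2's size factors turned the sign of Fkbp5 (0.0058) for stress in males and Kcnq5 (0.0049) in the interaction.

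The absence of a low-count filter turned the sign of Fkbp5 (0.00011) for stress in males.

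DESeq2 turned the sign of Fkbp5 (0.0057) for stress in males and Kcnq5 (0.0050) in the interaction.

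Voom with quality weights turned the sign of 10 gene values. Esr1 (0.034) and Pdyn (0.058) did so for stress in females. Fkbp5 (0.0043) did so for stress in males. Kcnq5 (0.068), Adcyap1r1 (-0.024) and Cyp19a1 (-0.35) did so in the interaction. Xist (0.19) did so for the average over the sexes. Adcyap1r1 (0.032) and Sst (0.030) did so in controls between the sexes. Nr3c1 (-0.046) did so in stressed mice between the sexes.

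The replicate block turned the sign of 5 gene values. Fos (-0.17) and Esr1 (0.15) did so for stress in females, Fkbp5 (0.019) in males and Kcnq5 (0.049) in the interaction. Crh (0.019) did so in controls between the sexes.

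The number set term turned the sign of Kcnq5 (-0.0059) for stress in females and Fkbp5 (0.0054) in males. It also turned Kcnq5 (0.029) in the interaction.

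Surrogate variables turned the sign of 31 gene values. Zic4 (-0.0026), Npy (-0.044), Adcyap1r1 (-0.0061), Sst (-0.031), Pdyn (0.0012) and Xist (0.019) did so for stress in females. Npy (0.086), Sst (0.041), Penk (0.031) and Xist (-0.0059) did so for stress in males. Npy (0.13), Crhr1 (-0.036), Sst (0.072), Penk (0.0023) and Xist (-0.025) did so in the interaction. Dnah12 (-0.0080), Npy (0.021), Kcnq3 (0.023), Esr1 (-0.044), Sst (0.0050), Penk (0.030) and Xist (0.0065) did so for the average over the sexes. Kcnq3 (0.0011), Kcnq5 (0.015), Adcyap1 (-0.0045) and Fkbp5 (-0.0046) did so in controls between the sexes. Mt1 (0.00086), Kcnq5 (0.014), Crhr1 (-0.0068), Adcyap1r1 (-0.039) and Nr3c1 (-0.039) did so in stressed mice between the sexes.

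Marker scores as covariates turned the sign of 31 gene values and 1 list value. Kcnq5 (-0.050), Adcyap1r1 (-0.013), Esr1 (0.058), Penk (-0.016) and Xist (0.092) did so for stress in females. Ttr (-0.70), Kcnj13 (-0.31), Igf2 (-0.089), Penk (0.024) and Xist (-0.064) did so for stress in males. Ttr (-1.36), Kcnj13 (-0.012), Kcnq5 (0.18), Penk (0.040) and Xist (-0.16) did so in the interaction. Ttr (-0.015), Igf2 (-0.11), F5 (-0.014), Kcnq3 (0.017), Adcyap1 (0.13), Adcyap1r1 (-0.00055), Penk (0.0041) and Xist (0.014) did so for the average over the sexes. Kcnq3 (0.038), Kcnq5 (0.046), Crh (0.072), Crhr1 (-0.022) and Pdyn (0.014) did so in controls between the sexes. Ttr (-0.52), Kcnq5 (0.22) and Adcyap1r1 (-0.073) did so in stressed mice between the sexes. The lists were choroid plexus in stressed mice between the sexes (adjusted p = 0.973).

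Leaving out the 5 libraries that stood apart turned the sign of 6 gene values. Esr1 (-0.0019) did so for the average over the sexes. Kcnq3 (0.032), Kcnq5 (0.0076) and Penk (0.0086) did so in controls between the sexes. Adcyap1r1 (-0.024) and Nr3c1 (-0.021) did so in stressed mice between the sexes.

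Leaving out those 5 libraries with the number set term turned the sign of 8 gene values. Kcnq3 (-0.019) and Kcnq5 (-0.017) did so for stress in males. Kcnq3 (-0.0018) did so in the interaction. Esr1 (-0.0091) did so for the average over the sexes. Kcnq3 (0.035), Kcnq5 (0.0081) and Penk (0.048) did so in controls between the sexes. Nr3c1 (-0.037) did so in stressed mice between the sexes.

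Leaving out MS5 with the number set term turned the sign of 6 gene values. Kcnq5 (-0.0012) did so for stress in females. Fkbp5 (0.042) and Xist (-0.0045) did so for stress in males. Ttr (-0.040) and Kcnq5 (0.025) did so in the interaction. Igf2 (-0.0076) did so for the average over the sexes.

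Leaving out the 5 libraries and MS5 with the number set term turned the sign of 8 gene values. Pdyn (0.00013) did so for stress in females. Kcnq3 (-0.0025), Kcnq5 (-0.023) and Fkbp5 (0.022) did so for stress in males. Kcnq3 (0.038), Kcnq5 (0.011) and Penk (0.052) did so in controls between the sexes. Nr3c1 (-0.030) did so in stressed mice between the sexes.

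Libraries numbered up to 5 alone turned the sign of 35 gene values and 6 list values. Cacna1i (0.077), Zic4 (-0.50), Crh (0.14), Adcyap1r1 (-0.015), Nr3c1 (-0.074), Fkbp5 (0.21), Fos (-0.27) and Pdyn (0.18) did so for stress in females. Kcnq3 (-0.094), Crh (0.15) and Esr1 (-0.083) did so for stress in males. Gpr17 (-0.067), Kcnq3 (-0.056), Crh (0.0015), Crhr1 (-0.084), Fkbp5 (-0.24) and Cyp19a1 (-0.17) did so in the interaction. Zic1 (-0.062), Zic2 (-0.035), Npy (0.21), Crh (0.14), Nr3c1 (-0.0028), Fkbp5 (0.094), Esr1 (-0.18), Sst (0.16), Penk (0.17) and Pdyn (0.0084) did so for the average over the sexes. Kcnq3 (0.054), Kcnq5 (0.049), Crh (0.035) and Pdyn (0.00035) did so in controls between the sexes. Kcnq3 (-0.0026), Crh (0.037), Fkbp5 (-0.027) and Fos (0.042) did so in stressed mice between the sexes. The lists were glucocorticoid target genes for stress in females (adjusted p = 0.667), septal neurons for stress in females (adjusted p = 0.0462), other potassium channels for stress in males (adjusted p = 0.877) and glucocorticoid target genes for the average over the sexes (adjusted p = 0.244). They were also GABA synthesis and receptors for the average over the sexes (adjusted p = 0.502) and interferon response and antigen presentation in stressed mice between the sexes (adjusted p = 0.0982).

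Libraries numbered 6 and above alone turned the sign of 24 gene values and 2 list values. Rpl4 (-0.046), Rpl17 (-0.16), Npy (-0.41), Kcnq5 (-0.20), Adcyap1 (0.014), Esr1 (0.21), Sst (-0.35), Penk (-0.55) and Xist (0.15) did so for stress in females. Fkbp5 (0.046) and Cyp19a1 (0.099) did so for stress in males. Drd2 (0.089), Kcnq5 (0.24), Penk (0.13), Pdyn (0.064) and Xist (-0.11) did so in the interaction. Kcnq5 (-0.078), Adcyap1 (0.21), Xist (0.098) and Ddx3y (0.13) did so for the average over the sexes. Fkbp5 (-0.13) and Fos (-0.067) did so in controls between the sexes. Kcnq5 (0.026) and Nr3c1 (-0.0064) did so in stressed mice between the sexes. The lists were cytosolic ribosomal proteins for stress in females (adjusted p = 9.95e-07) and circadian clock genes for the average over the sexes (adjusted p = 0.983).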

Other observations

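The correlation of expression with transcript length in each library, a test chosen after seeing the results, ran from -0.415 to 0.330 outside the 5 libraries that stood apart and from -0.397 to -0.240 within them. Group means were 0.0655 ± 0.184 (SD) in control females, -0.0124 ± 0.253 in stressed females, -0.0505 ± 0.218 in control males and 0.173 ± 0.108 in stressed males. The exact p was 0.0122 for stress in males, 0.443 in females and 0.0623 for sex in stressed mice. Across genes, the sex effect in controls followed length at -0.181.

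The 45S precursor Rn45s stood at 5894 CPM in libraries numbered up to 5 and at 16347 in the others, Mir6236 at 232 and 702 CPM and Mir2137 at 0.0024 and 15.4. The 5 libraries that stood apart held 12268 to 54291 CPM of Rn45s against 1189 to 27309 in the others.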
